A study of Mus musculus with 18 samples.

How the data were processed

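RNA of the liver, the intestine and the lung was sequenced from mice 24 h after cecal ligation and puncture, with or without inhaled hydrogen, 3 libraries per organ and treatment. Per the labels, RNA was extracted with miRNeasy Micro columns and libraries were made with the TruSeq stranded mRNA kit. Per the submitters' processing notes, TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cufflinks 2.2.1 were used with mouse genome build mm10. The annotation and the options were not given in the sources used here. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) made by the authors, 1 column per library, with 24346 gene symbols, each present once. Columns sum to different totals, so they are not TPM, and no further scaling across libraries is stated. The file of control lung 2 holds a second column whose values equal those of control lung 3 (0 differ), and that column was not used. Of the symbols, 4694 are at 0 in every library. The groups follow the sample titles. In the description fields, H2 replicates 2 and 3 carry another number in the name of the gas, which was read as an error of numbering.

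FPKM were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear models with an empirical Bayes trend, two-sided). Each organ was fitted alone on its 6 libraries, over genes with a mean FPKM of at least 1. The joint test of the mean of the 3 organ changes and the tests of differences between organs used all 18 libraries in 1 fit with 1 mean per group. P values were adjusted by Benjamini and Hochberg over all tested genes, and genes under an adjusted p of 0.05 were called. The groups, tests, filters and lists were fixed before the data were examined. With 3 against 3 libraries an exact permutation test of a single gene cannot give a p under 0.1, so all p values come from limma's moderated test. The fits were tested on simulated data. With 100 genes changed by a log2 of 2, 91% were called in the liver, 86% in the intestine and 94% in the lung, and at a log2 of 1 they were 74%, 36% and 51%. Only genes with a mean log2(FPKM + 1) above 2 were changed, and noise was drawn independently for each gene. Real genes move together, so these shares need not hold for the real libraries.

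Gene lists, 31 of processes and 29 of cell types, hold 1224 symbols, of which 1210 were found, 1 of them by a synonym. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of the organ. The joint change was tested with camera alone, after the data were seen. Adjustment of members over the list alone was also made. The genes named follow a rule. In each organ it takes the called genes whose groups do not overlap, the 10 largest rises and falls, leaving out predicted and small RNA genes. Where fewer pass, it adds up to 5 genes per direction with the smallest p, given as values. It takes up to 4 members with the smallest p of each list described. It takes in every organ the panel Il6, Tnf, Il1b, Il10, Cxcl1, Cxcl2, Ccl2, Nos2, Hmox1, Saa1, Lcn2 and S100a8. In the joint and difference tests it takes the 10 genes with the smallest p. Named beyond this rule after their values were seen are Mir1901, Mir6516, the list members of the joint test, the genes called with 1 mean over the organs, and the marker genes given per library. Some genes that the rule takes are not reported here.

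Files of FPKM hold no read counts. An implied depth per library was estimated from the peak of FPKM times transcript length that marks 1 fragment, over genes with 1 transcript, and it ran from 8.87 to 16.3 M fragments. It is used to compare libraries and gives no interval for single values. Gene positions and transcript lengths come from GENCODE vM21 for mm10, matched by symbol. Other settings were run 1 at a time. They were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, quantile normalization, median-of-ratios scaling, empirical Bayes without trend and with a robust fit, array weights, small RNA genes left out, a replicate block, all 18 libraries in 1 fit for the organs, each library left out, camera with an estimated correlation, and fry. Chosen after seeing the data were replicate 1 as a batch term, 1 mean over the organs per group and number, and list tests of the differences between organs.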

Results

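Poly(A) RNA of the liver, the intestine and the lung was sequenced from septic mice that did or did not inhale hydrogen gas. Male C57BL/6 mice, 9 weeks old, underwent cecal ligation and puncture, a surgical model of sepsis from gut bacteria. H2 mice breathed 7% hydrogen without interruption directly after surgery, in a shared box, so that housing and gas go together. Control mice had the same surgery without the gas. Tissue was taken 24 h after surgery, which gave 18 libraries in 6 groups of n = 3. Groups were taken from the sample titles, and the labels do not state which organs came from the same mouse. Sham-operated mice are not analysed here. The deposited values were FPKM of 24346 gene symbols. The depth implied by genes at 1 fragment ran from 8.87 M fragments in H2 intestine 2 to 16.3 M in H2 lung 2. In the lung it was 10.5, 13.03 and 12.3 M in the control libraries and 13.9, 16.3 and 15.5 M in the H2 libraries. Changes below are log2 of H2 over control on FPKM + 1, each ± SE with n = 3 per group and organ, and group means are FPKM ± SD.

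Each library expressed the markers of its labelled organ. The hepatocyte gene Alb lay between 9335 FPKM (control liver 2) and 21978 FPKM (control liver 1) in the liver and at most 5.95 FPKM elsewhere. The enterocyte gene Vil1 was at least 332 FPKM in the intestine and at most 0.450 FPKM elsewhere. The surfactant gene Sftpc was at least 20779 FPKM in the lung and at most 1.17 FPKM elsewhere. The club cell secretoglobin Scgb1a1 measured 4.30, 5.07, 3.22 and 5.27 FPKM in control liver 1, H2 liver 1, control intestine 1 and H2 intestine 1, and 0 in liver and intestine libraries 2 and 3. The summed FPKM of H2 intestine 2 was 1143000, against 712860 to 850610 in the other 5 intestine libraries. On an axis that runs from 0 at the mean of the control libraries to 1 at the mean of the H2 libraries, each library placed without itself, control liver 2 scored 0.80 and control lung 3 scored 0.76. The H2 libraries of these organs scored 0.70 to 0.93 in the liver and 0.78 to 0.84 in the lung. The other control libraries scored -0.01 and -0.14 in the liver, and -0.20 and 0.18 in the lung. In the intestine the control libraries scored 0.13, 0.56 and 0.27 and the H2 libraries 0.53, 0.86 and 0.44.

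**Figure D1:**
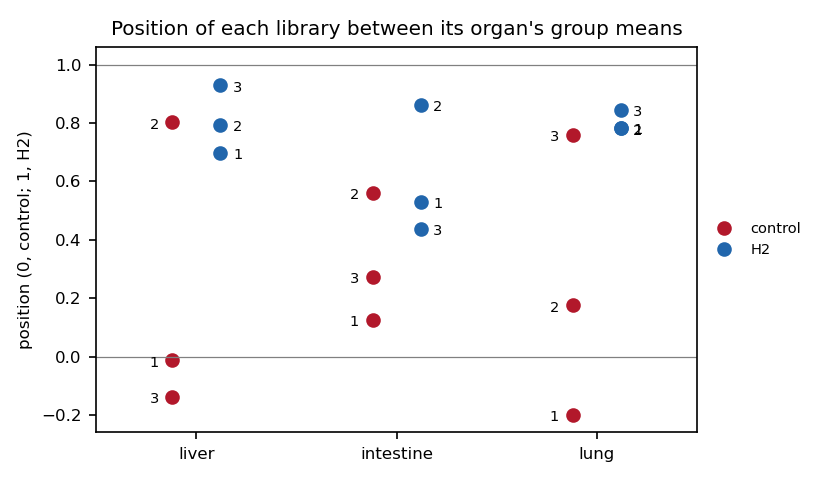
Position of each of the 18 libraries (points, numbered by replicate) on the axis of its organ from the control mean (0) to the H2 mean (1), a unitless score taken across all tested genes. Control liver 2 (0.80) and control lung 3 (0.76) sit near the H2 libraries of their organs.

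The title of the series asks about inflammatory signalling, and the first comparison takes the mean H2 change over the 3 organs. The neutrophil chemokine gene Cxcl2 fell by a log2 of 2.65 (SE 0.67), the monocyte chemokine gene Ccl2 by 1.85 (SE 0.40), Il6 by 2.15 (SE 0.65), Il1b by 1.49 (SE 0.45) and the anti-inflammatory cytokine gene Il10 by 1.43 (SE 0.25). Of the 12 inflammatory genes chosen before the data were examined, 7 fell and 0 rose. The other 2 that fell were Hmox1, heme oxygenase 1, at -0.92 ± 0.26, and Lcn2, an iron-binding acute-phase protein, at -0.90 ± 0.21. Tnf (-0.67 ± 0.24), Cxcl1 (-1.49 ± 0.50), Nos2 (-0.06 ± 0.20), Saa1 (-0.35 ± 0.18) and S100a8 (-0.26 ± 0.32) did not pass. Nos2 changed sign in some alternative fits.

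Among 13362 tested genes 1285 passed, with 586 higher and 699 lower, and 4101 had an unadjusted p under 0.05. Whether more genes fell than rose depends on the scaling, with 691 higher and 620 lower after median-of-ratios scaling, 711 and 693 after quantile normalization and 622 and 611 at a pseudocount of 5. The same sign in all 3 organs was seen for 1109 of the 1285 genes (86.3%). Choosing genes by their mean change over the same organs favours equal signs, and no share over all tested genes was taken. Among the called genes with the smallest p were Mir1901, Atp2a2, Maff, Psg18, Ifi205, Cd300lg, Csrnp1, Serpina3f and Rtn4rl2. Mir1901 and Psg18 owe their mean change to the intestine. The stress-induced transcription factors Maff (-0.89 ± 0.12) and Csrnp1 (-0.86 ± 0.12), the interferon-inducible Ifi205 (-1.29 ± 0.18), the serine protease inhibitor Serpina3f (-2.48 ± 0.36), the calcium pump gene Atp2a2 (-0.52 ± 0.06) and Rtn4rl2 (-1.08 ± 0.16) were lower in each organ. Maff measured 3.87 ± 1.25 FPKM in control to 0.664 ± 0.190 in H2 in the liver, 16.8 ± 3.58 FPKM in control to 11.8 ± 0.522 in H2 in the intestine and 76.3 ± 15.6 FPKM in control to 46.2 ± 5.42 in H2 in the lung. Serpina3f measured 155 ± 120 FPKM in control to 4.86 ± 0.787 in H2 in the liver.

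Over all tested genes 4.39% rose and 5.23% fell, and both shares depend on the scaling named above. The lists were fixed before the data were examined. Camera, a test of a list against all other genes, was applied to the joint change after the data were seen and called 19 of 59 lists at a preset correlation of 0.01, 2 higher and 17 lower. With an estimated correlation camera called 0, the lowest adjusted p being 0.498, with 3 lists at an unadjusted p under 0.05. All 19 had an adjusted p of 0.498 to 0.675 with an estimated correlation. They hold the 11 lists described first, up to glycolysis and hypoxia, the enterocyte list, and the neutrophil, cell cycle, ribosomal protein, immediate early, adipocyte, muscle and Paneth cell lists, with the enterocyte and Paneth cell lists higher. The drug metabolism and endothelial marker lists were not called. The members named per list, up to 4, were chosen by p after the joint values were seen. Of 30 tested genes of the NF-kB and TNF response, 16 fell over all genes and 23 when adjusted over the list alone, among them Sod2 -0.96 ± 0.17, Ier3 -1.71 ± 0.32, Cebpb -0.72 ± 0.14 and Rela -0.48 ± 0.09. Of 32 acute-phase and STAT3 target genes, 14 fell, and 18 when adjusted over the list alone, with the plasma proteins Orm1 -1.38 ± 0.21, A2m -0.47 ± 0.07 and Saa2 -1.02 ± 0.20 and the metalloreductase Steap4 at -0.9998 ± 0.19. Orm1 and Saa2 did not fall in the liver (0.06 and 0.03), and A2m did not in the intestine (0.00898). Of 16 cytokine genes 7 fell, and 12 fell and 1 rose when adjusted over the list alone. The interleukin-1 receptor antagonist Il1rn was at -2.00 ± 0.37, Tgfb1 at -0.54 ± 0.13 and the granulocyte growth factor Csf3 at -2.76 ± 0.69. Of 29 chemokine genes 9 fell and 1 rose, and 13 fell and 1 rose when adjusted over the list alone, with Ccl5 -1.89 ± 0.31, Ccl17 -1.04 ± 0.19, Cxcl10 -2.08 ± 0.39 and Ccl4 -2.18 ± 0.45. Of 28 Toll-like receptor and inflammasome genes 7 fell, and 12 when adjusted over the list alone, including the lipopolysaccharide co-receptor Cd14 (-1.71 ± 0.32), the signalling inhibitor Irak3 (-0.99 ± 0.22), Casp4 (-0.65 ± 0.16, but 0.11 in the intestine) and Lbp (-0.53 ± 0.13, but 0.19 in the liver). Of 32 interferon response genes 5 fell, and 14 when adjusted over the list alone (Ifit3b -0.94 ± 0.18, Ifit3 -1.19 ± 0.23, Irf7 -0.98 ± 0.23 and Rsad2 -1.21 ± 0.30). Irf7 was higher in the intestine (0.41). Of 29 interferon-gamma GTPase and antigen presentation genes 8 fell, and 11 when adjusted over the list alone (Gbp5 -1.16 ± 0.17, Iigp1 -1.23 ± 0.26, Nlrc5 -0.43 ± 0.10 and Gbp3 -1.19 ± 0.28).

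Of 22 genes of endothelial activation and adhesion 8 fell and 1 rose, and 10 fell and 2 rose when adjusted over the list alone. The leukocyte-capturing selectins Selp (-1.95 ± 0.31) and Sele (-1.18 ± 0.26) and the adhesion molecule Icam1 (-0.82 ± 0.17) were among the falls. Of 29 extracellular matrix genes 9 fell, and 11 when adjusted over the list alone, with Timp1 -1.54 ± 0.30, Mmp14 -0.89 ± 0.17, Thbs1 -1.22 ± 0.28 and Lox -0.76 ± 0.18. Metallothioneins bind zinc and copper, and 3 of 6 genes of their list fell both over all genes and when adjusted over the list alone: Mt2 -1.52 ± 0.26, Mt1 -1.42 ± 0.24 and Slc39a14 -0.62 ± 0.19, the last without a fall in the intestine (0.04). Of 28 glycolysis and hypoxia genes 4 fell, by both counts (Pfkfb3 -1.24 ± 0.21, Hk2 -0.76 ± 0.18, Hif1a -0.98 ± 0.24 and Slc2a1 -0.86 ± 0.23). Of 30 drug metabolism genes 6 rose, and 8 when adjusted over the list alone (Fmo5 1.15 ± 0.26, Ugt2b5 0.87 ± 0.20, Ugt2b36 0.68 ± 0.16 and Fmo1 0.93 ± 0.26). The list was not called by camera (adjusted p = 0.0750, and adjusted p = 0.675 with an estimated correlation). Ugt2b5 and Ugt2b36 were at 0 in the lung, and Fmo1 did not rise in the intestine (-0.04). Of 19 endothelial marker genes 4 rose, and 6 rose and 2 fell when adjusted over the list alone (Ptprb 0.61 ± 0.13, Kdr 0.57 ± 0.13, Emcn 0.78 ± 0.19 and Tek 0.78 ± 0.22), and Ptprb and Kdr were lower in the intestine (-0.18 and -0.10). This list was not called by camera either (adjusted p = 0.173, and adjusted p = 0.675 with an estimated correlation). Of 18 enterocyte marker genes 4 rose by both counts (Dpp4 0.76 ± 0.16, Fabp1 1.55 ± 0.41, Slc26a3 0.27 ± 0.08 and Mgam 0.41 ± 0.12), Slc26a3 without a rise in the liver (-0.01).

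This fit counts the 18 libraries as independent animals. With 1 mean over the organs for each group and replicate number, a setting chosen after seeing the data, 16 genes passed, 15 of them among the 1285. They include Serpina3f -2.48 ± 0.24, Socs1 -1.27 ± 0.13, Mt1 -1.42 ± 0.15, Mt2 -1.52 ± 0.16, Orm1 -1.38 ± 0.15 and Selp -1.95 ± 0.23, with the SE of this fit. The 7 panel genes called over 18 libraries are not among them, at adjusted p = 0.0764 (Il10) to 0.138 (Hmox1). The count over 18 libraries was 387 without control liver 1, 2632 without control liver 2, 312 without control liver 3, 429 without H2 liver 1, 614 without H2 liver 2, 406 without H2 liver 3, 497 without control intestine 1, 572 without control intestine 3, 668 without H2 intestine 2, 446 without control lung 1, 482 without control lung 2, 2814 without control lung 3, 466 without H2 lung 1, 386 without H2 lung 2 and 479 without H2 lung 3. Among the panel genes, Il10 and Ccl2 kept their calls without any 1 library. Lcn2 lost its call in 1 of the 18 such fits (control liver 3 left out), Cxcl2 in 12, Hmox1 in 13, Il6 in 14 and Il1b in 15. In these fits each of the 7 genes stayed lower in H2.

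**Figure D2:**
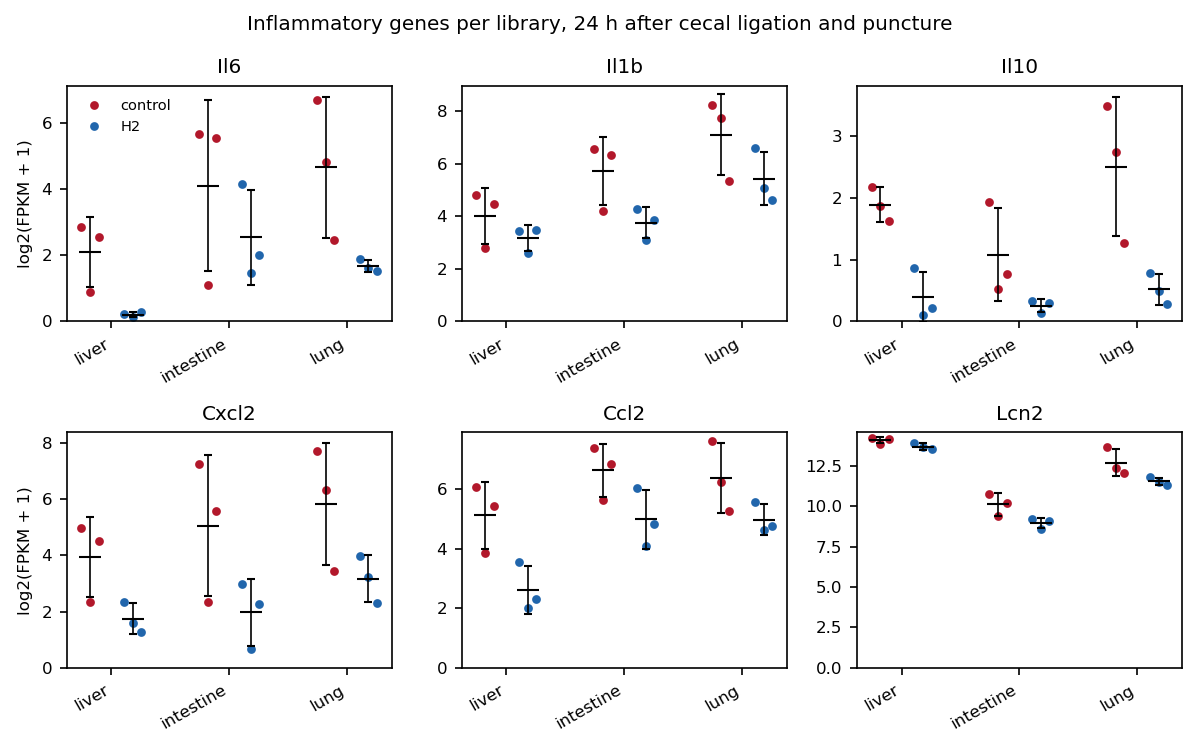
Expression as log2(FPKM + 1) of 6 inflammatory genes in each library (points), with group means and SD (bars, n = 3), for control and H2 in the 3 organs. The H2 mean lies below the control mean in each organ for all 6 genes.

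In the liver, H2 went with more mRNA of the endothelial receptor gene Cd300lg. It rose from 0.599 ± 0.0663 FPKM in control to 2.80 ± 0.152 in H2 (log2 1.25 ± 0.11, adjusted p = 0.0383). Every H2 library lay above every control library. In mm10 Cd300lg spans chromosome 11 from 102041509 to 102055620 on the plus strand. Of 10041 tested genes 2 passed, while 2113 had an unadjusted p under 0.05 where 502 would be expected by chance. The groups did not overlap for 2537 genes (25.3%), where chance gives 10%. Genes are not independent, and neither count was made for other splits of the libraries, so neither is a test of the treatment.

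The uncalled genes with the smallest p are given as values. Toward higher levels in H2 these were the myeloid receptor Cd300ld (1.11 ± 0.12), the granule protease Prtn3 (1.43 ± 0.17), Tcea3 (1.07 ± 0.13), the aldehyde oxidase Aox3 (1.93 ± 0.23) and the Kupffer cell lectin Clec4f (1.501 ± 0.21). Toward lower levels they were the sphingomyelin synthase Sgms1 (-1.20 ± 0.13), Rtn4rl2 (-1.12 ± 0.12), the protease inhibitor A2m (-1.17 ± 0.15), the activin receptor Acvr1b (-1.31 ± 0.18) and the oncostatin M receptor Osmr (-0.77 ± 0.11). Of the 12-gene panel 10 were tested in the liver, 9 were lower in H2, 5 had an unadjusted p under 0.05 and 0 passed. Il6 measured 4.02 ± 2.81 FPKM in control and 0.153 ± 0.0542 in H2, Il10 2.75 ± 0.735 FPKM in control and 0.354 ± 0.407 in H2, Ccl2 40.7 ± 26.2 FPKM in control and 5.87 ± 4.18 in H2 and Cxcl2 18.8 ± 13.5 FPKM in control and 2.54 ± 1.40 in H2. Il1b (-0.84 ± 0.53), Hmox1 (-0.35 ± 0.17), Lcn2 (-0.39 ± 0.15) and S100a8 (-0.57 ± 0.43) were also lower. Cxcl1 (-0.06 ± 0.22) and Saa1 (0.07 ± 0.12) lay near 0, and both changed sign in alternative fits. Tnf (1.16 and 0.576 FPKM) and Nos2 (0.499 and 0.130 FPKM) were too low to test.

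Camera called 20 of 40 lists in the liver, 8 higher and 12 lower in H2, at the preset correlation. With an estimated correlation it called 0, the lowest adjusted p being 0.584, with 0 lists at an unadjusted p under 0.05. Fry, which tests a list's own direction, called 0 at a lowest adjusted p of 0.133, with 10 lists at an unadjusted p under 0.05. Counts of members are those adjusted over the list alone, with 0 over all genes. Of 17 immediate early genes, the fast transcriptional response to stimuli, 8 fell (Maff -1.52 ± 0.22, Ier2 -1.12 ± 0.20, Egr1 -1.79 ± 0.34 and Btg2 -0.61 ± 0.15). The list was lower (adjusted p = 1.7e-05, and adjusted p = 0.584 with an estimated correlation). Of 26 NF-kB and TNF response genes 10 fell (Tnip1 -0.77 ± 0.13, Sod2 -0.95 ± 0.20, Birc3 -0.87 ± 0.21 and Ier3 -2.65 ± 0.67), and the list was lower (adjusted p = 1.7e-05, and adjusted p = 0.584 with an estimated correlation). Of 11 cytokine genes 5 fell (Il1rn -2.35 ± 0.35, Il10 -1.49 ± 0.24, Il6 -1.90 ± 0.47 and Il33 -2.39 ± 0.69), with the list lower (adjusted p = 0.005005, and adjusted p = 0.584 with an estimated correlation). Of 20 glycolysis and hypoxia genes 3 fell (Hif1a -1.31 ± 0.25, Pfkfb3 -1.83 ± 0.38 and Aldoa -0.93 ± 0.20), with the list lower (adjusted p = 0.00121, and adjusted p = 0.584 with an estimated correlation). Of 18 Toll-like receptor and inflammasome genes 4 fell (Cd14 -2.81 ± 0.48, Casp4 -1.01 ± 0.19, Irak3 -0.88 ± 0.18 and Tlr2 -0.71 ± 0.19), with the list lower (adjusted p = 0.0140, and adjusted p = 0.584 with an estimated correlation). Of 15 endothelial activation genes 6 fell and 1 rose (Procr -1.18 ± 0.26, Selp -2.11 ± 0.48 and Thbd -1.21 ± 0.32), with the list lower (adjusted p = 0.0123, and adjusted p = 0.584 with an estimated correlation).

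Lists that were higher in the H2 liver hold resident cell markers and hepatocyte functions. Of 24 monocyte and macrophage markers 11 rose and 2 fell. The Kupffer cell genes Clec4f 1.501 ± 0.21 and Vsig4 2.17 ± 0.35 and the complement gene C1qc (0.74 ± 0.12) rose while Cd14 (-2.81 ± 0.48) fell (adjusted p = 0.00629, and adjusted p = 0.584 with an estimated correlation). Of 19 endothelial markers 6 rose and 1 fell (Ptprb 1.28 ± 0.25, Plvap 0.49 ± 0.12, Emcn 0.68 ± 0.16 and Kdr 1.01 ± 0.26), with the list higher (adjusted p = 0.00636, and adjusted p = 0.584 with an estimated correlation). Of 17 bile acid genes 7 rose and 1 fell: the sterol hydroxylase Cyp8b1 (1.01 ± 0.20) and the uptake carriers Slc10a1 (1.73 ± 0.36) and Slco1b2 (2.21 ± 0.57) rose and the exporter subunit Slc51b (-1.01 ± 0.27) fell (adjusted p = 0.00789, and adjusted p = 0.584 with an estimated correlation). Of 31 coagulation and complement genes 5 rose and 3 fell, the falls including Procr, with the list higher (adjusted p = 0.00789, and adjusted p = 0.584 with an estimated correlation). The cytochrome P450 list (adjusted p = 0.0123, and adjusted p = 0.679 with an estimated correlation), the fatty acid oxidation list (adjusted p = 0.0140, and adjusted p = 0.723 with an estimated correlation) and the hepatocyte list (adjusted p = 0.0282, and adjusted p = 0.679 with an estimated correlation) were higher with 0 members passing. Of 9 enterocyte markers 2 rose and 1 fell (Mgam 0.39 ± 0.11, Dpp4 0.88 ± 0.27 and Car4 -2.70 ± 0.46), with the list higher (adjusted p = 0.0376, and adjusted p = 0.609 with an estimated correlation). Lower too were the interferon response (adjusted p = 0.00223, and adjusted p = 0.679 with an estimated correlation), interferon-gamma (adjusted p = 0.00789, and adjusted p = 0.679 with an estimated correlation) and ribosomal protein lists (adjusted p = 0.0428, and adjusted p = 0.801 with an estimated correlation), with 0 members passing. Of 15 neutrophil genes 3 fell (Clec4e -1.76 ± 0.43, Fpr2 -0.79 ± 0.20 and Clec4d -1.34 ± 0.37), with the list lower (adjusted p = 0.005005, and adjusted p = 0.651 with an estimated correlation). Of 20 chemokine genes 5 fell and 2 rose, with the smallest p at Ccl6 1.09 ± 0.17, Ccl5 -2.88 ± 0.62, Ccl2 -2.51 ± 0.62 and Cxcl12 1.12 ± 0.30, and the list was lower (adjusted p = 0.0303, and adjusted p = 0.584 with an estimated correlation). Of 5 genes of the metallothionein list the zinc carrier Slc39a4 fell (-0.77 ± 0.19), with the list lower (adjusted p = 0.0264, and adjusted p = 0.584 with an estimated correlation).

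The liver count moved most with control liver 2, the control library near the H2 libraries. The count was 0 without control liver 1, 2834 without control liver 2, 1 without H2 liver 1, 0 without H2 liver 2 and 0 without H2 liver 3, and it was 3 without control liver 3. Cd300lg lost its call in 5 of the 6 such fits. For lists, leaving out control liver 2 ended the calls of the Toll-like receptor, interferon-gamma, metallothionein, chemokine, cytochrome P450, ribosomal, macrophage, endothelium, hepatocyte and enterocyte lists, and the count of lists fell from 20 to 11. Control liver 1 left out ended those of the chemokine, ribosomal and enterocyte lists. Control liver 3 left out ended those of the metallothionein, fatty acid, coagulation, ribosomal, hepatocyte and enterocyte lists. Without H2 liver 2 the chemokine, interferon, interferon-gamma, endothelial activation, ribosomal and hepatocyte calls ended, without H2 liver 1 the enterocyte call, and without H2 liver 3 the fatty acid call.

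**Figure D3:**
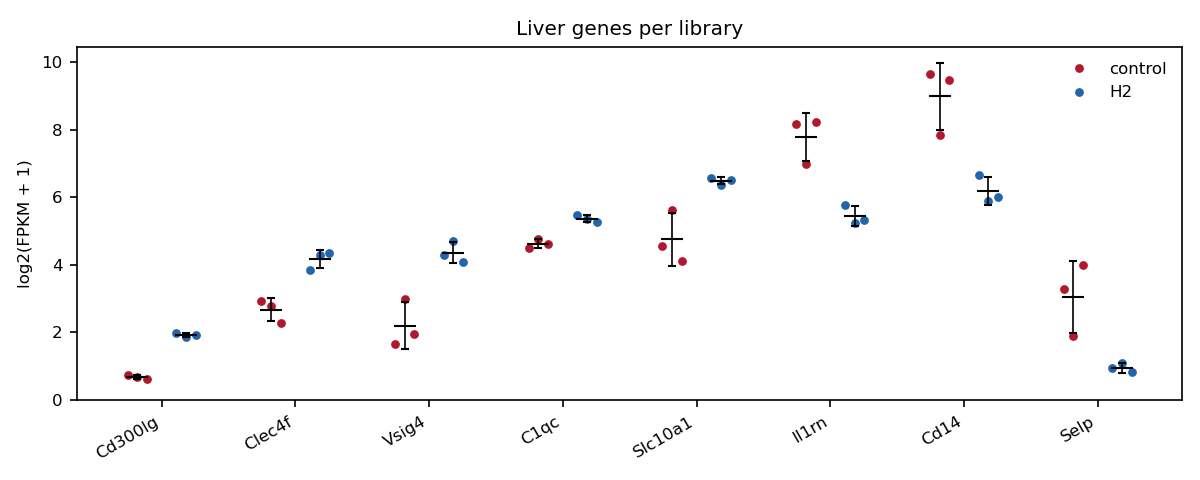
Expression as log2(FPKM + 1) of 8 liver genes in each library (points), with group means and SD (bars, n = 3). Every H2 library lies above every control library for Cd300lg, Clec4f, Vsig4, C1qc and Slc10a1, and below every control library for Il1rn, Cd14 and Selp.

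In the intestine, H2 went with lower NF-kB target, matrix and fat cell genes and with higher respiratory chain genes, as lists at the preset correlation of camera. None of these calls held, with adjusted p = 0.361 with an estimated correlation for the NF-kB list and 0.746 for the matrix, fat cell and respiratory chain lists. The NF-kB targets Icam1 (-1.43 ± 0.29) and Ier3 (-1.69 ± 0.38) and the matrix genes Thbs1 (-2.08 ± 0.48) and Timp1 (-1.73 ± 0.40) fell when adjusted over their lists alone. The fat cell genes Cfd (-4.17 ± 1.27), Retn (-3.01 ± 0.86), Adipoq (-2.91 ± 0.86) and Fabp4 (-1.59 ± 0.42) fell by the same count. Over all genes, 1 of 11910 passed, the small RNA gene Mir1901, while 1485 had an unadjusted p under 0.05 where 596 would be expected by chance. Mir1901, named although small RNA genes lie outside the naming rule, measured 3140 ± 912 FPKM in control and is listed at 0 in the 3 H2 libraries. The 78-base gene lies on chromosome 18 of mm10 from 11840361 to 11840438 on the minus strand, over an exon of Cables1 on the opposite strand. The groups did not overlap for 2300 genes (19.3%), where chance gives 10%, and as in the liver neither count was made for other splits.

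The uncalled genes with the smallest p are given as values. Toward higher levels they were the steroid dehydrogenase Hsd17b6 (1.142 ± 0.666 FPKM in control to 12.8 ± 4.26 in H2), Psg18 (4.93 ± 1.137 FPKM in control to 19.4 ± 3.36 in H2), the phosphodiesterase-like Smpdl3b (1.21 ± 0.15), the nuclease Dnase1 (2.64 ± 0.32) and Slc17a4 (1.49 ± 0.23). Toward lower levels they were BB123696 (-1.72 ± 0.22), Serpina3f (-1.26 ± 0.17), the interferon-induced GTPase Gbp5 (-1.55 ± 0.21), the MAP kinase phosphatase Dusp2 (-1.45 ± 0.20) and the acute-phase protein Orm1 (-2.04 ± 0.33). Of the 12-gene panel 11 were tested, 10 were lower in H2, 5 had an unadjusted p under 0.05 and 0 passed. Cxcl2 measured 67.5 ± 76.1 FPKM in control and 3.78 ± 3.17 in H2, Ccl2 111 ± 59.5 FPKM in control and 36.2 ± 25.4 in H2, Il1b 64.1 ± 40.7 FPKM in control and 13.3 ± 5.48 in H2 and Lcn2 1199 ± 537 FPKM in control and 505 ± 108 in H2. Il6 (-1.57 ± 1.24), Tnf (-0.65 ± 0.34), Cxcl1 (-2.30 ± 0.98), Hmox1 (-0.88 ± 0.52), Nos2 (-0.17 ± 0.41) and S100a8 (-0.29 ± 0.63) were lower as well, and the last 2 changed sign in alternative fits. Saa1 was higher (0.46 ± 0.23). Il10 (1.32 and 0.197 FPKM) was too low to test.

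Camera called 17 of 52 lists in the intestine, 3 higher and 14 lower. With an estimated correlation it called 0 (lowest adjusted p = 0.361, 3 lists at an unadjusted p under 0.05), and fry called 0 (lowest adjusted p = 0.112, 5 lists at an unadjusted p under 0.05). At the preset correlation, 7 of the 10 ways to split the 6 libraries 3 against 3, the real one included, called as many lists. Counts of members are adjusted over the list alone, with 0 over all genes. Of 30 NF-kB and TNF response genes 8 fell (Icam1 -1.43 ± 0.29, Tnfaip2 -1.30 ± 0.29, Ier3 -1.69 ± 0.38 and Zc3h12a -1.22 ± 0.31), with the list lower (adjusted p = 1.7e-08, and adjusted p = 0.361 with an estimated correlation). Of 29 extracellular matrix genes 10 fell (Mmp14 -1.31 ± 0.29, Thbs1 -2.08 ± 0.48, Timp1 -1.73 ± 0.40 and Fn1 -1.23 ± 0.29), with the list lower (adjusted p = 1.7e-07, and adjusted p = 0.746 with an estimated correlation). Of 22 acute-phase genes 2 fell (Orm1 -2.04 ± 0.33 and Steap4 -1.41 ± 0.32), with the list lower (adjusted p = 1.7e-07, and adjusted p = 0.361 with an estimated correlation). Of 16 cytokine genes 7 fell and 1 rose (Spp1 -2.19 ± 0.57, Csf2 -1.43 ± 0.40, Csf1 -0.95 ± 0.28 and Il1a -1.97 ± 0.59), with the list lower (adjusted p = 4.6e-05, and adjusted p = 0.746 with an estimated correlation). Of 30 chemokine genes 2 fell (Ccl5 -1.58 ± 0.27 and Cxcl10 -2.40 ± 0.46), with the list lower (adjusted p = 4.2e-04, and adjusted p = 0.547 with an estimated correlation). Of 19 endothelial activation genes 5 fell (F3 -1.40 ± 0.28, Icam1 -1.43 ± 0.29 and Selp -1.17 ± 0.29), with the list lower (adjusted p = 7.0e-05, and adjusted p = 0.746 with an estimated correlation). Of 16 glucocorticoid response genes 5 fell (Pdk4 -1.46 ± 0.31, Mt2 -1.65 ± 0.41, Dusp1 -1.37 ± 0.39 and Klf9 -0.80 ± 0.23), with the list lower (adjusted p = 3.2e-04, and adjusted p = 0.746 with an estimated correlation). Of 6 metallothionein and zinc transport genes 2 fell (Mt2 -1.65 ± 0.41 and Mt1 -1.47 ± 0.37), with the list lower (adjusted p = 0.0392, and adjusted p = 0.746 with an estimated correlation).

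Of 10 adipocyte markers 4 fell (Fabp4 -1.59 ± 0.42, Retn -3.01 ± 0.86, Adipoq -2.91 ± 0.86 and Cfd -4.17 ± 1.27), with the list lower (adjusted p = 7.2e-05, and adjusted p = 0.746 with an estimated correlation). Of 6 neuron and glia markers 2 fell (Uchl1 -1.32 ± 0.36 and Tubb3 -0.91 ± 0.27), with the list lower (adjusted p = 7.0e-04, and adjusted p = 0.608 with an estimated correlation). The neutrophil list was lower with 0 of 23 members passing (adjusted p = 8.0e-05, and adjusted p = 0.772 with an estimated correlation). With 0 passing, lower as well were the dendritic cell list (adjusted p = 0.0300, and adjusted p = 0.608 with an estimated correlation) and the immediate early list (adjusted p = 0.00118, and adjusted p = 0.746 with an estimated correlation). The coagulation list, of which F3 fell, was lower too (adjusted p = 0.0294, and adjusted p = 0.746 with an estimated correlation). The 44 oxidative phosphorylation genes, which build the respiratory chain, were higher as a list with 0 members passing (adjusted p = 5.9e-08, and adjusted p = 0.746 with an estimated correlation). Their smallest p belonged to Ndufs8 0.73 ± 0.26, Atp5o 0.55 ± 0.21, Ndufa9 0.53 ± 0.22 and Sdhb 0.52 ± 0.22. The transcripts of this list are short (median 636 bases), and no matching on length was made in the intestine. The Paneth cell list of antimicrobial secretory genes was higher with 0 of 12 passing (adjusted p = 4.2e-04, and adjusted p = 0.746 with an estimated correlation). The enterocyte list was higher with 0 of 19 passing (adjusted p = 0.00660, and adjusted p = 0.924 with an estimated correlation). H2 intestine 2 held the highest values of the enterocyte gene Fabp2 (3746 FPKM) and of the Paneth cell gene Defa24 (50576 FPKM).

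The number of intestinal genes moved with each library: it was 2 without control intestine 1, 28 without control intestine 2, 5 without control intestine 3, 8 without H2 intestine 1, 2 without H2 intestine 2 and 18 without H2 intestine 3. The enterocyte and dendritic cell calls ended without control intestine 2 or H2 intestine 2, the metallothionein call without control intestine 1, H2 intestine 2 or H2 intestine 3, and the coagulation call without H2 intestine 2. Under quantile normalization the Paneth cell, enterocyte and dendritic cell calls ended.

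In the lung, H2 went with lower interferon-induced, acute-phase, cell division, respiratory chain and ribosomal protein genes and with higher alveolar type 1 cell genes, as lists at the preset correlation of camera. None of these calls held, with adjusted p = 0.569 with an estimated correlation for each of the 6 lists. The interferon-induced genes Zbp1 -1.81 ± 0.33 and Ifit3 -1.87 ± 0.42, the acute-phase genes Hpx -2.01 ± 0.21 and Saa2 -2.75 ± 0.45 and the mitotic genes Birc5 -1.66 ± 0.28 and Ube2c -1.22 ± 0.18 fell when adjusted over their lists alone. Over all genes, 1 of 13424 passed, the small RNA gene Mir6516, while 3095 had an unadjusted p under 0.05 where 671 would be expected by chance. Mir6516, named although it lies outside the naming rule, is listed at 0 in the 3 control libraries and measured 112 ± 16.8 FPKM in H2. A few fragments per library could give these values. The 110-base gene lies on chromosome 11 of mm10 from 117077348 to 117077457 on the plus strand, within an exon of Snhg20. The groups did not overlap for 4026 genes (29.99%), where chance gives 10%, and as in the liver neither count was made for other splits.

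The uncalled genes with the smallest p are given as values. Toward higher levels they were the ciliary gene Cc2d2a (0.74 ± 0.10), the growth cone protein Gap43 (1.73 ± 0.25), Spink4 (1.56 ± 0.23), Abi3bp (0.94 ± 0.14) and the basement membrane collagen Col4a4 (0.85 ± 0.13). Toward lower levels they were the heme carrier Hpx (19.4 ± 4.88 FPKM in control to 4.05 ± 0.881 in H2), the cathelicidin Camp (292 ± 27.7 FPKM in control to 146 ± 2.56 in H2), Agr2 (-1.11 ± 0.13) and Plac8 (-1.42 ± 0.17). All 12 panel genes were tested, 10 were lower in H2, 8 had an unadjusted p under 0.05 and 0 passed. Il6 measured 45.2 ± 51.8 FPKM in control and 2.21 ± 0.422 in H2, Il10 5.76 ± 4.37 FPKM in control and 0.445 ± 0.253 in H2, Hmox1 133 ± 76.4 FPKM in control and 40.7 ± 2.71 in H2 and Saa1 617 ± 440 FPKM in control and 175 ± 15.5 in H2. Tnf (-0.94 ± 0.51), Il1b (-1.68 ± 0.83), Cxcl1 (-2.10 ± 0.77), Cxcl2 (-2.66 ± 1.03), Ccl2 (-1.40 ± 0.58) and Lcn2 (-1.15 ± 0.40) were lower as well. Nos2 (0.37 ± 0.22) and S100a8 (0.09 ± 0.27) were higher, and S100a8 changed sign in alternative fits.

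Camera called 20 of 54 lists in the lung, 3 higher and 17 lower. With an estimated correlation it called 0 (lowest adjusted p = 0.569, 1 list at an unadjusted p under 0.05), and fry called 0 (lowest adjusted p = 0.0788, 14 lists at an unadjusted p under 0.05). At the preset correlation, 7 of the 10 ways to split the 6 libraries 3 against 3, the real one included, called as many lists. Counts of members are adjusted over the list alone, with 0 over all genes. Of 32 interferon response genes 18 fell (Zbp1 -1.81 ± 0.33, Ifit3b -1.89 ± 0.39, Ifit3 -1.87 ± 0.42 and Ifit1 -1.72 ± 0.40), with the list lower (adjusted p = 1.7e-11, and adjusted p = 0.569 with an estimated correlation). Of 29 interferon-gamma GTPase and antigen presentation genes 14 fell (Nlrc5 -0.78 ± 0.13, Iigp1 -2.23 ± 0.45, Gbp5 -1.75 ± 0.38 and Psmb8 -0.76 ± 0.18), with the list lower (adjusted p = 1.4e-07, and adjusted p = 0.569 with an estimated correlation). Of 27 acute-phase genes 15 fell (Hpx -2.01 ± 0.21, Saa2 -2.75 ± 0.45, Orm3 -1.34 ± 0.23 and Orm1 -2.16 ± 0.43), with the list lower (adjusted p = 2.7e-09, and adjusted p = 0.569 with an estimated correlation). Of 29 chemokine genes 8 fell and 1 rose (Cxcl9 -1.37 ± 0.27, Ccl17 -1.67 ± 0.35, Ccl4 -2.49 ± 0.57 and Ccl9 -1.53 ± 0.37), with the list lower (adjusted p = 3.4e-05, and adjusted p = 0.569 with an estimated correlation). Of 36 cell cycle genes 21 fell (Ccna2 -0.85 ± 0.12, Ccnb2 -1.05 ± 0.15, Ube2c -1.22 ± 0.18 and Birc5 -1.66 ± 0.28), with the list lower (adjusted p = 4.7e-10, and adjusted p = 0.569 with an estimated correlation). Of 43 ribosomal protein genes 30 fell (Rps2 -0.50 ± 0.10, Rpl38 -0.49 ± 0.10, Rplp2 -0.56 ± 0.13 and Rpsa -0.42 ± 0.10), with the list lower (adjusted p = 1.4e-14, and adjusted p = 0.569 with an estimated correlation). Of 44 oxidative phosphorylation genes 26 fell (Uqcrq -0.67 ± 0.12, Cox5a -0.64 ± 0.12 and Ndufb8 -0.47 ± 0.10), with the list lower (adjusted p = 8.2e-13, and adjusted p = 0.569 with an estimated correlation). Both of the last lists hold short transcripts, with median lengths of 658 and 636 bases against 1388 over all tested genes, and depth was higher in each H2 lung library than in each control.

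Of 30 NF-kB and TNF response genes 0 passed, with the list lower (adjusted p = 7.0e-08, and adjusted p = 0.569 with an estimated correlation) and the smallest p at Cebpb -0.93 ± 0.21, Cebpd -1.01 ± 0.26, Nfkbib -0.59 ± 0.16 and Bcl3 -1.07 ± 0.31. Of 30 Toll-like receptor and inflammasome genes Pycard fell (-1.27 ± 0.23), with the list lower (adjusted p = 1.2e-04, and adjusted p = 0.626 with an estimated correlation). The cytokine list was lower with 0 of 16 passing (adjusted p = 0.0286, and adjusted p = 0.657 with an estimated correlation), as was the NRF2 antioxidant list with 0 of 30 (adjusted p = 9.2e-04, and adjusted p = 0.569 with an estimated correlation). The glycolysis list (adjusted p = 0.0194, and adjusted p = 0.618 with an estimated correlation) and the unfolded protein response list (adjusted p = 0.0347, and adjusted p = 0.569 with an estimated correlation) were lower with 0 passing. Of 12 gluconeogenesis and urea cycle genes 2 fell, the arginase Arg1 (-2.56 ± 0.57) and Got1 (-0.72 ± 0.17), with the list lower (adjusted p = 0.0270, and adjusted p = 0.569 with an estimated correlation). Of 13 skeletal and cardiac muscle markers 10 fell (Ckm -1.59 ± 0.25, Myh6 -1.44 ± 0.24, Myl4 -1.39 ± 0.32 and Myl7 -1.51 ± 0.37), with the list lower (adjusted p = 1.2e-05, and adjusted p = 0.569 with an estimated correlation). Of 26 monocyte and macrophage markers 7 fell and 1 rose, with Cx3cr1 up (1.02 ± 0.22) and Fcgr4 -1.07 ± 0.26, Ly6c2 -0.83 ± 0.21 and Ctss -0.88 ± 0.22 down (adjusted p = 0.00737, and adjusted p = 0.569 with an estimated correlation). The T cell list was lower with 0 of 13 passing (adjusted p = 0.0251, and adjusted p = 0.569 with an estimated correlation). Of 12 alveolar type 1 cell markers, the flat gas-exchange cells, 5 rose (Ager 0.44 ± 0.11, Vegfa 0.35 ± 0.10, Emp2 0.63 ± 0.19 and Clic5 0.94 ± 0.28), with the list higher (adjusted p = 0.00332, and adjusted p = 0.569 with an estimated correlation). The fibroblast list (adjusted p = 0.0481, and adjusted p = 0.569 with an estimated correlation) and the cytochrome P450 list (adjusted p = 0.0473, and adjusted p = 0.677 with an estimated correlation) were higher with 0 passing.

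Among the libraries left out, control lung 3, the control library near the H2 libraries, moved the lung count most. The count was 4 without control lung 1, 2 without control lung 2, 3295 without control lung 3, 3 without H2 lung 1 and 2 without H2 lung 3. The cytokine, cytochrome P450, T cell and fibroblast calls ended without control lung 1, the cytochrome P450, gluconeogenesis, unfolded protein response and fibroblast calls without control lung 3, and the fibroblast call without H2 lung 1. The cytokine, cytochrome P450 and unfolded protein response calls ended without H2 lung 2, and the gluconeogenesis and T cell calls without H2 lung 3. Median-of-ratios scaling ended the cytochrome P450 and fibroblast calls, and quantile normalization the glycolysis and unfolded protein response calls. A mean FPKM of at least 5 ended the cell cycle, cytokine, gluconeogenesis, glycolysis and unfolded protein response calls. Array weights ended the alveolar type 1 cell, T cell, fibroblast, cytochrome P450, gluconeogenesis, glycolysis and unfolded protein response calls.

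**Figure D4:**
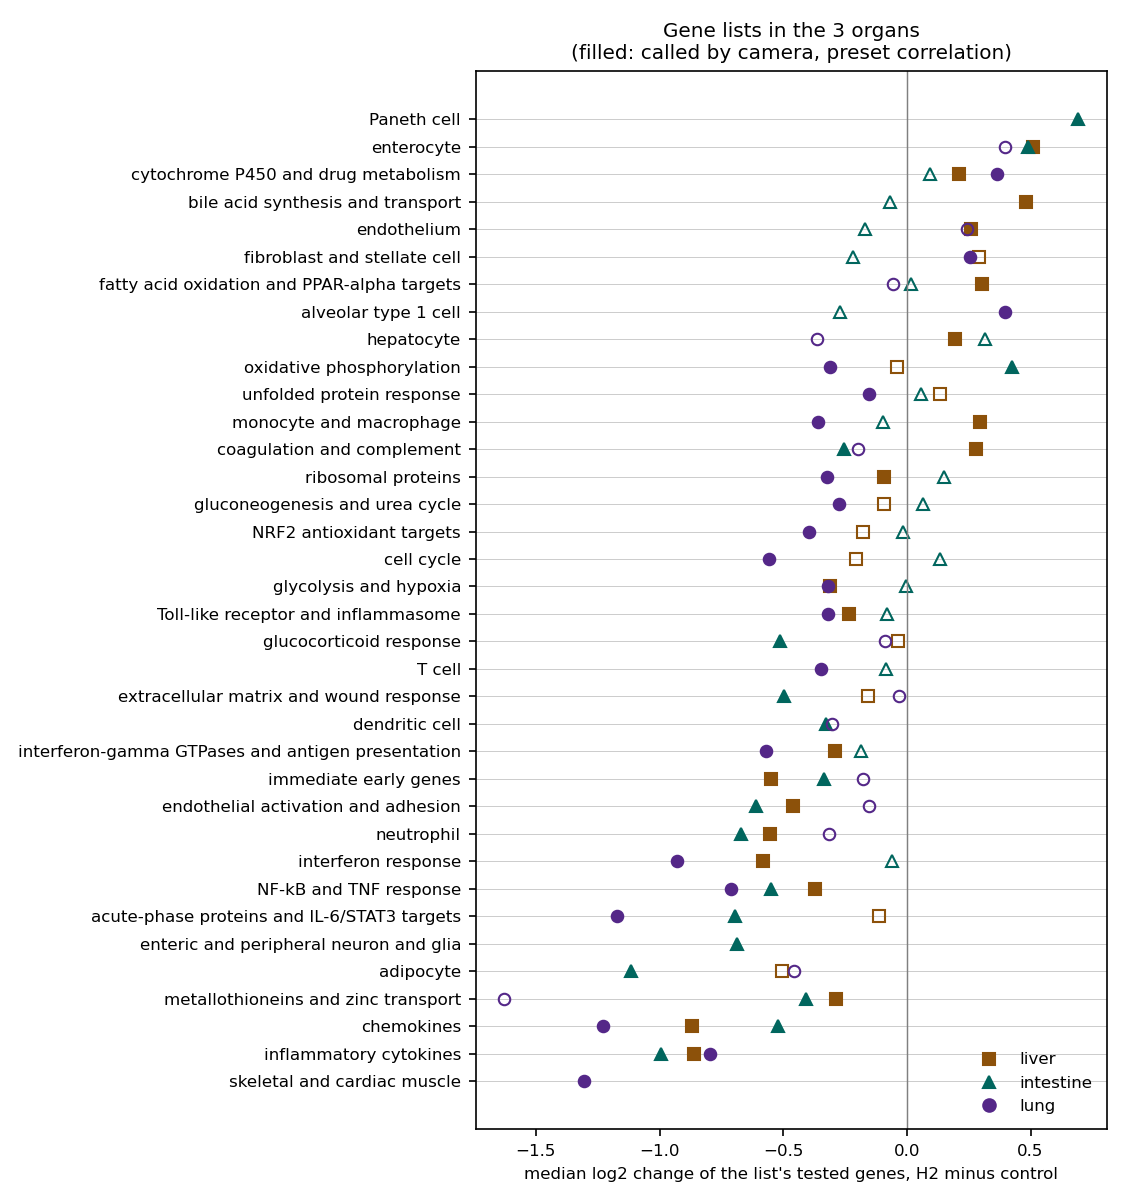
Median log2 change (H2 over control) of the tested members of each gene list called in at least 1 organ, by organ. Filled symbols mark lists called by camera at the preset correlation, and 0 of them pass with an estimated correlation.

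Whether the H2 change differed between organs was tested as the change in 1 organ minus that in another. The change of the Kupffer cell gene Clec4f in the liver exceeded those in the intestine and the lung (1.501 ± 0.23 and 1.44 ± 0.22). Its change was 0 in the intestine and 0.0575 in the lung, so the difference restates the liver change, uncalled in the liver fit. The hydroxysteroid dehydrogenase Akr1c6 was alike (2.93 ± 0.42 and 2.93 ± 0.41), and both genes lay under the expression filter in the other organs. Between liver and intestine 31 of 11848 genes differed, 19 of them more positive in the liver. Those with the smallest p also hold Mir1901 (11.58 ± 0.20), Psg18 (-1.76 ± 0.20), BB123696 (1.70 ± 0.24), Mxra8 (1.52 ± 0.23), A2m (-1.18 ± 0.18), AI427809 (-1.93 ± 0.31) and the endothelin Edn2 (-1.29 ± 0.21). In the liver Mir1901 and Edn2 did not change, and Psg18 and BB123696 barely did (0.0225 and -0.0172). The differences of these genes restate the change in the intestine, which for Mir1901 may rest on 1 or 2 fragments per control library. Between liver and lung 61 of 13051 differed, 41 of them more positive in the liver. Prtn3 (2.94 ± 0.32), the fatty acid carrier Fabp7 (1.47 ± 0.22), the creatine synthesis enzyme Gatm (1.72 ± 0.28) and Art1 (2.08 ± 0.34) were more positive in the liver. For Art1 this restates its fall in the lung (-2.08, against -0.00227 in the liver). Sema3a (-1.83 ± 0.29) and the carbonic anhydrase Car4 (-3.32 ± 0.55) were more positive in the lung. Between intestine and lung 188 of 13554 differed, 112 of them more positive in the intestine. Psg18 (1.78 ± 0.19), the fatty acid elongase Elovl6 (1.61 ± 0.22), Gm10684 (1.58 ± 0.23) and the cell cycle gene Cdca3 (1.55 ± 0.23) were more positive in the intestine. Mir1901 (-11.58 ± 0.20), BB123696 (-1.83 ± 0.23), Gap43 (-2.48 ± 0.35), Abi3bp (-1.33 ± 0.19), Antxr1 (-1.38 ± 0.21) and Ism1 (-1.70 ± 0.26) were more positive in the lung. The changes of Mir1901 and Psg18 in the lung were 0, so their differences restate the change in the intestine.

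These counts rest on single libraries. Between liver and intestine the count was 11 without control liver 1, 803 without control liver 2, 9 without control liver 3, 17 without H2 liver 1, 12 without H2 liver 2, 9 without H2 liver 3, 13 without control intestine 1, 99 without control intestine 2, 10 without control intestine 3, 76 without H2 intestine 1, 11 without H2 intestine 2 and 439 without H2 intestine 3. Between liver and lung it was 9 without control liver 1, 564 without control liver 2, 7 without control liver 3, 6 without H2 liver 1, 10 without H2 liver 2, 2 without H2 liver 3, 28 without control intestine 2, 24 without control intestine 3, 35 without H2 intestine 1, 37 without H2 intestine 2, 34 without H2 intestine 3, 18 without control lung 1, 19 without control lung 2, 702 without control lung 3, 39 without H2 lung 1, 7 without H2 lung 2 and 6 without H2 lung 3. Between intestine and lung it was 81 without control liver 1, 69 without control liver 3, 63 without H2 liver 1, 57 without H2 liver 2, 50 without H2 liver 3, 39 without control intestine 1, 300 without control intestine 2, 28 without control intestine 3, 40 without H2 intestine 2, 913 without H2 intestine 3, 57 without control lung 1, 52 without control lung 2, 1187 without control lung 3, 35 without H2 lung 2 and 30 without H2 lung 3.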

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

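The tests of library position, depth and shared animals, of small RNA values, overlapping genes and fragment multiples, of length and scaling, of mice split whole and of the joint lists were chosen after the result was seen, and those of zeros falling on 1 group and of the other splits of the libraries before.

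Control liver 2 and control lung 3 lay near the H2 libraries of their organs. An exchange with an H2 library needs an H2 library out of place, and the lowest H2 scores, 0.699 in the liver and 0.781 in the lung, lay above those of the other controls, which argues against it. Low depth is argued against as well, since these libraries, at 11.9 and 12.3 M fragments, were not the shallowest of their organs. A control label on an H2 library may account for control liver 2, whose score of 0.802 is within the H2 range, and stays open for control lung 3 at 0.759, below the lowest H2 score by less than the SD of the 3. That 1 control mouse gave both also stays open, as their deviations from the group means correlate across genes at 0.350 (next highest control liver and lung pair 0.222), and control intestine 2 correlates with both (0.270 and 0.310), but the labels do not say which organs share a mouse, genes are not independent replicates, and no biological explanation such as a milder illness was tested.

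Mir1901 was at 0 in all H2 intestine libraries and Mir6516 at 0 in all control lung libraries. A change of Snhg20, a gene over Mir6516 on its strand, is argued against at a log2 of 0.29 (Gm26083, which also overlaps, is not analysed here), while for Mir1901 stray reads of Cables1 on the other strand, at -0.69, and a change of Gm6277 on the same strand, at 0.27 but near the floor (mean 0.443 FPKM), stay open. Unstable values of small RNA genes stay open too, as 0.387 of those tested in the 2 organs were at 0 in 1 library and above 100 FPKM in another of the same group. Zeros that fall on 1 group by chance may account for both genes, since among 23 small RNA genes with exactly 3 zeros, the zeros filled 1 group in 2, where chance gives 10% (exact binomial p = 1). These 2 are Mir1901 and Mir6516 themselves, and a test on 23 genes has little power against a higher share. Mir1901 values in control may rest on 1 or 2 fragments per library, because FPKM times depth stood at whole multiples of the lowest within 0.00506. That of Mir6516 in H2 stood at 1, 1.493 and 1.495 of its lowest. These are not whole multiples, but a few fragments per library could give them too. No biological explanation was tested beyond the treatment itself.

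Ribosomal protein and oxidative phosphorylation genes were lower in the H2 lung, with list medians of -0.32 and -0.31. Scaling by a few abundant genes is argued against, as the medians stayed at -0.32 and -0.30 after median-of-ratios scaling. Gene length and expression level may account for the ribosomal list, since random lists matched on both had medians from -0.33 to -0.15 in their central 95%. The match left out only the list's own members, so the other list and unlisted ribosomal protein genes could be drawn. It therefore cannot separate length and level from a change that such genes share. For the oxidative phosphorylation list, matched in the same way, gene length and expression level cannot be told apart from a change of the list itself. Its median lay outside the matched range of -0.30 to -0.09 by less than the SD of the list's leave-1-out medians (0.0341). That margin was set after the result was seen in place of a plain bound at the range. Treatment as a biological cause stays open, as cage and depth go with the groups.

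Other splits of the libraries were fitted in the same way. Within an organ, 10 splits of 6 libraries can never give a share under 0.05. The real split called 2 genes in the liver, 1 in the intestine and 1 in the lung, and the highest other split 2, 4 and 4, with 2, 7 and 6 of the 10 splits, the real one included, calling as many. For lists the real split called 20, 17 and 20 and the highest other 15, 24 and 25, with 1, 7 and 7 splits calling as many. Chance can thus not be excluded for the number of lists in any organ. Over the 3 organs together, 1 of 100 drawn splits, the real one, gave as many as 1285 genes, and the highest other gave 119. This excludes chance only if the 18 libraries came from separate mice, which the labels do not say. For the differences between organs, 2 of 100 splits gave as many in each case, the highest other calling 162 genes for liver against intestine, 1076 for liver against lung and 534 for intestine against lung. Each of these splits exchanges all labels of 1 organ, which turns the test of the difference into a test of the shared change, and the first also exchanges control liver 2 and H2 liver 2. For the joint lists 33 of the same 100 splits called as many as the real 19, the highest other calling 27, so chance cannot be excluded for their number. With each replicate number of a group taken as 1 mouse and split whole over the organs, 10 splits can never give a share under 0.05. The real one alone gave as many genes in all 4 tests (1 of 10 each), with 1285 joint genes against a highest other of 7, and 31, 61 and 188 differences against 14, 7 and 5. For the joint lists 3 of the 10 gave as many, 19 against a highest other of 24.

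Differences between organs under the same contrast drew a closer look because the interaction test passed. Between liver and intestine 31 genes differed, among them, as log2 changes in the liver minus those in the intestine, Mir1901 11.58, Psg18 -1.76, Akr1c6 2.93, BB123696 1.70, Mxra8 1.52, A2m -1.18, Clec4f 1.501, AI427809 -1.93 and Edn2 -1.29. Between liver and lung 61 genes differed, among them, as liver minus lung values, Prtn3 2.94, Akr1c6 2.93, Clec4f 1.44, Fabp7 1.47, Sema3a -1.83, Gatm 1.72, Art1 2.08 and Car4 -3.32. Between intestine and lung 188 genes differed, among them, as intestine minus lung values, Mir1901 -11.58, Psg18 1.78, BB123696 -1.83, Elovl6 1.61, Gap43 -2.48, Gm10684 1.58, Abi3bp -1.33, Cdca3 1.55, Antxr1 -1.38 and Ism1 -1.70. Clec4f, Akr1c6, Mir1901, Psg18 and Edn2 had little or no change in 1 of the organs compared, so their differences restate the change in the other organ. The lung airway gene Scgb1a1, which belongs to neither organ, was present in control liver 1 (4.30 FPKM), H2 liver 1 (5.07), control intestine 1 (3.22) and H2 intestine 1 (5.27), and at 0 in their replicates 2 and 3.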

How the results depend on the processing

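Settings named here were planned except replicate 1 as a batch term, 1 mean over the organs and the list tests of differences and of the joint change, chosen after seeing the data, and the cause of a shift was not tested unless stated. Counts of called genes or lists follow, with the reported value first. Liver genes (2): 0 at pseudocount 0.1, without filter, at FPKM of at least 5 (Cd300lg is then not tested), with the replicate block and with the batch term, 1 under quantile normalization, 2520 with array weights and 445 with all 18 libraries in 1 fit. Intestine genes (1): 2 with the robust fit, 11 with array weights, 0 without small RNA genes, which removes Mir1901, 3 with the block, and 312 in 1 fit. Lung genes (1): 2 without filter, 7137 with array weights, 0 without small RNA genes, which removes Mir6516, and 818 in 1 fit. Joint genes (1285): 5655 with array weights and 16 with 1 mean over the organs, which leaves 3 values against 3. Liver against intestine (31): 12 and 70 at pseudocounts 0.1 and 5, 65 without filter, 6 at FPKM of at least 5, 47 under median-of-ratios, 51 robust, 1217 with array weights, 49 without small RNA genes and 53 with the block. Liver against lung (61): 14, 159, 122 and 6 for the first 4 of these and 979 with array weights. Intestine against lung (188): 31, 477, 406 and 43 for the same 4, 57 under quantile normalization, 79 under median-of-ratios and 2797 with array weights. Liver lists (20): 10 with array weights. With an estimated correlation or fry, 0 lists were called in any organ. Joint lists (19): 0 with an estimated correlation. Leaving out 1 library gave 0 to 2834 genes in the liver, 2 to 28 in the intestine, 1 to 3295 in the lung, 312 to 2814 jointly, 9 to 803, 2 to 702 and 28 to 1187 for the 3 differences in the order above, and 11 to 21, 16 to 22 and 16 to 24 lists in the organs and 18 to 21 jointly. Choosing the highest of repeated symbols was not run, since none repeats.

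Directions reversed in genes that passed no test, and ranges are those over libraries left out. Cxcl1 in the liver ran from -0.21 to 0.13, with 0.0014 under quantile normalization, 0.13 without control liver 3 and 0.0688 without H2 liver 1. Saa1 in the liver ran from -0.0201 to 0.16, the reversed value being that without control liver 1. Nos2 in the intestine ran from -0.55 to 0.18, with 0.50 under array weights, 0.10 without control 2 and the highest without H2 intestine 3. S100a8 in the intestine ran from -1.05 to 0.37, the highest without control 1, and in the lung from -0.13 to 0.29, with -0.0866 without control 1 and the lowest without H2 lung 2. Nos2 jointly ran from -0.18 to 0.0603, with 0.26 under array weights, 0.0189 without control liver 1, 0.0318 without control intestine 2 and the highest without H2 intestine 3. Over named genes, 4591 of 5101 organ values kept direction and call, 481 became calls, 19 lost them and 10 reversed. Jointly 3347 of 4318 kept them and 958 lost the call, and of 884 differences 822 kept them. Depth may limit genes near 1 FPKM and small RNA genes, where 1 fragment is worth many FPKM, but its effect by expression level was not tested.

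Not every same-numbered pair of control and H2 libraries deviated together, so the numbers were not taken as pairs. The correlations were 0.33, -0.08 and 0.03 in the liver, 0.16, -0.11 and -0.03 in the intestine and -0.01, 0.12 and 0.01 in the lung, and only liver 1, intestine 1 and lung 2 correlated best with their own number. Replicates 1 of liver and intestine also share Scgb1a1 over both groups. Sftpc was alike, at 1.13 and 1.17 FPKM in control and H2 liver 1 and 0.562 and 0.727 in control and H2 intestine 1. It was at 0 in replicates 2 and 3 of both organs. In the lung, Reg3b was at 4.59 and 4.88 FPKM in control and H2 lung 1 and at most 0.632 in the others. Alb and Defa24 went another way and were highest among lung libraries in control lung 2 (5.95 and 0.528 FPKM). Replicates 1 thus have something in common whose cause was not tested. Across organs, same-numbered control liver and intestine libraries deviated together at 0.245, 0.270 and 0.135, each the highest for its number. In the H2 group these were 0.0657, -0.0199 and -0.00653, between control liver and lung 0.175, -0.0726 and -0.255, and between control intestine and lung 0.231, -0.116 and -0.0756. Whether a number marks 1 mouse over organs therefore stays open. With the number as a replicate block, 0 genes were called in the liver, 3 in the intestine and 927 jointly. It ended the calls of the lung fibroblast list (adjusted p = 0.0527, and 0.0542 with the batch term) and the liver enterocyte list (adjusted p = 0.0594). Over 19 settings the fibroblast call held in 8, the liver enterocyte call in 10, the liver ribosomal call in 8 and the lung cytochrome P450 call in 10.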

Other observations

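Genes of 4 further lists that passed in the joint test are given here, beside 4.39% higher and 5.23% lower over all genes, shares that depend on the scaling, and the genes named and the list tests of differences between organs were chosen after the result was seen. Of 27 unfolded protein response genes 5 fell over all genes, and 7 fell and 1 rose when adjusted over the list alone, with the transcription factors Xbp1 -0.57 ± 0.11 and Atf4 -0.50 ± 0.11 among them. Of 28 reactive oxygen enzymes 3 rose and 4 fell, and 4 rose and 4 fell when adjusted over the list alone. Sod2, the mitochondrial superoxide dismutase, fell (-0.96 ± 0.17), as did the phagocyte oxidase subunit Cybb (-0.45 ± 0.12), and the peroxiredoxin Prdx2 (0.40 ± 0.10) and the oxidase Nox4 (0.71 ± 0.20) rose. Of 33 NRF2 antioxidant targets 2 rose and 4 fell, and 3 rose and 6 fell when adjusted over the list alone, among them Gsr (-0.69 ± 0.18), Txnrd1 (-0.57 ± 0.16) and Ugdh (0.29 ± 0.09, but -0.15 in the lung). Without any 1 library the calls of Sod2, Xbp1 and Atf4 held in all 18 fits. They were lost in 10 of 18 for Prdx2 and Gsr, in 12 for Cybb, in 13 for Nox4 and Ugdh and in 14 for Txnrd1. Of 37 coagulation and complement genes 6 fell, and 3 rose and 8 fell when adjusted over the list alone, with the clot starter F3 (-0.61 ± 0.15, but 0.10 in the liver) and the urokinase receptor Plaur (-1.42 ± 0.36). Leaving out 1 library ended the call of F3 in 11 of 18 fits and that of Plaur in 9. As lists, camera called none of the 4 jointly, in the order above (adjusted p = 0.546, 0.527, 0.0517 and 0.982, and adjusted p = 0.850, 0.774, 0.675 and 0.9999 with an estimated correlation).

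As lists, the H2 changes differed between organs by camera in 18 of 53 lists for liver against intestine, 18 of 53 for liver against lung and 15 of 59 for intestine against lung, and in 0 with an estimated correlation, where 1, 5 and 3 had an unadjusted p under 0.05. Oxidative phosphorylation genes were higher in the intestine and lower in the lung (mean difference 0.71, adjusted p = 2.1e-22, and adjusted p = 0.484 with an estimated correlation). Interferon response genes differed between the same organs (mean difference 1.03, adjusted p = 1.5e-07, and adjusted p = 0.701 with an estimated correlation). Monocyte and macrophage markers were more positive in the liver than in the lung (mean difference 0.62, adjusted p = 1.2e-06, and adjusted p = 0.465 with an estimated correlation). Acute-phase genes were less lowered in the liver than in the lung (mean difference 0.83, adjusted p = 5.2e-07, and adjusted p = 0.492 with an estimated correlation).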
